A study of Mus musculus with 6 samples.

How the data were processed

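RNA was measured by sequencing in epithelial cells isolated from the colon of male Apc Min/+ mice, a strain that carries a truncating mutation of 1 copy of the tumour suppressor Apc and develops intestinal adenomas. Per the labels' protocols, mice of 5 to 6 weeks received atorvastatin at 20 mg/kg, or 2% Tween 80 as vehicle, by gavage on alternate days, and total RNA was prepared for Illumina sequencing by a standard protocol. Each group had 3 libraries. The labels number the libraries as replicates and do not say whether each came from a separate animal. The p-values of single genes therefore measure the spread between these libraries, which could be partly technical.

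The deposited values were FPKM (fragments normalized to gene length and to the mapped total), 1 value per gene and library for 52550 Ensembl gene identifiers. The unit was read from the values, since the totals differed between libraries (407857 to 430832) and no column was whole-numbered. Per the submitters' processing notes, FastQC 0.11.2, Bowtie (no version given) and the mm10 build were used. The quantification tool, the annotation, the strand setting and the treatment of reads that map to several places were not given in the sources used here. The mitochondrial genes mt-Co2, mt-Co3 and mt-Nd4l and their nuclear copies were listed at ratios of 1 to 1.01 in every library. Reads shared between near-identical copies were thus given to each copy for at least some genes. The ratios do not tell whether such reads were counted in full at each copy or divided evenly.

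The sequencing depth is unknown, because FPKM values carry no read totals. Among genes shorter than 150 bases, the commonest non-zero value, shared by 28 to 39 genes per library, put the relative depth at 0.996 to 1.14 times that of control replicate 1, with control replicate 3 the deepest. Of the values at or above that step, 6.99% to 8.9% lay within 0.01 of a whole multiple of it. A read gives a different FPKM at each gene length, so this share would be low in any case. It does not tell whether the values came from whole reads. Whole reads were not recovered, and no count-based test or counting interval was used. The relative depth assumes that the commonest value stands for the same gene length and number of reads in each library. FPKM divides by gene length and library total, and the share of the total taken by mitochondrial transcripts (30.3% to 33.2%) therefore scales all other genes. Values near 1 FPKM rest on few reads, and their precision is known only through the spread between libraries.

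The tests of genes and gene lists were chosen before the data were examined, and some tests of explanations after, as stated below. The design named a count model for counts and, for FPKM, a fit with limma 3.58.1 in R 4.3.3, and the latter was used. Genes with at least 1 FPKM in at least 3 of the 6 libraries were kept (11644 genes), and log2(FPKM + 1) was compared between atorvastatin and control with limma's trended and robust empirical Bayes test, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with low values. The ± after a fold change is the standard error, and the ± after an FPKM value is the SD of 3 libraries. Gene names came from a gene table that named 99.72% of the identifiers, and coordinates from GENCODE release M21 on the GRCm38 assembly, which mm10 denotes.

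A set of 34 gene lists, covering statin, lipid, xenobiotic, tryptophan, interleukin 17 and WNT biology and the cell types an epithelial isolate could hold, was tested with limma's camera at a preset correlation of 0.01, adjusted over the 31 lists with a tested member. Camera with an estimated correlation, and fry, were run beside it. The estimated correlation between genes was 0.577 for the interferon-stimulated list, 0.569 for proliferation and 0.823 for T and NK cells, but -0.0259 for enteroendocrine genes. Where the estimate lies above 0.01, the p-values at the preset correlation count correlated genes as nearly independent. They are then too small as measures of the spread between libraries. For enteroendocrine genes camera's unadjusted p also rose, from 1.9e-07 to 0.00545, though the estimate lies below 0.01. Correlation between genes does not account for that rise, so the p-value at the preset correlation may be too small there as well. Genes are named by a rule fixed in advance. It takes the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 1 FPKM and no overlap between groups, and the 5 smallest p-values in each direction. It adds up to 4 members with the smallest p from each list, which may be left out for lists that did not pass. Apc, Hmgcs1, Sqle, Insig1, Cyp1a1, Il17a, Il17ra, Lgr5, Axin2, Mki67, Muc2, Epcam and Ptprc are named always. Some genes the rule selects are not reported here, and predicted genes are not named unless among the smallest p-values.

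The fit was tested on simulated data drawn from the means and SDs of the 11644 genes, for the same comparison. Of 50 genes changed by a log2 size of 0.5, 32 were recovered, with 46 of 50 at a size of 1, 45 of 50 at 1.5 and 50 of 50 at 2. Among 11414 unchanged genes there were 9 false calls. Each gene was drawn independently from a normal distribution, so these figures leave out correlation between genes and effects shared within a library. They do not measure how reliable the calls in the real data are. Alternatives covered the pseudocount, the filter, the scaling between libraries, quality weights, a replicate block, the threshold and each library left out in turn. List means were also fitted by least squares with the group and 1 score per library, the mean log2(FPKM + 0.1) of the T and NK cell list or, chosen after the data were seen, the mean log2 FPKM of the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 or (for the MHC class II list) the mean log2(FPKM + 0.1) of 11 B cell, plasma cell, macrophage and dendritic cell genes. The scores differed between the groups, so these intervals are wide. Plots were drawn with matplotlib.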

Results

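Colon epithelial cells of Apc Min/+ mice were profiled after gavage with atorvastatin, a statin, which inhibits cholesterol synthesis, or with vehicle, in 3 libraries per group. The series concerns statins, microbial tryptophan catabolites and colorectal cancer, and this comparison asks how the drug alters gene expression in the colon epithelium. Each library listed 11456 to 11655 genes at 1 FPKM or more, and the FPKM totals ran from 407857 to 430832. Over the tested genes, Pearson correlations of log2 values (across genes, which are not independent replicates) were 0.989 to 0.990 within control, 0.990 to 0.992 within atorvastatin and 0.984 to 0.989 between the groups. The first principal component held 35.3% of the variance and separated the groups, with a gap between the nearest libraries of 40.8% of the component's range. That gap was 27% of the range over the 500 most variable genes.

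With atorvastatin, a group of interferon-inducible and antigen-presentation genes was lower, and a smaller group was higher that included a cytochrome P450, DNA replication genes and the hormone gene Gcg. Of 11644 tested genes, 47 passed limma's test at an adjusted p under 0.05, 18 higher and 29 lower, with absolute log2 fold changes of 0.40 to 2.04. In all 47 the groups did not overlap, as was the case for 2105 tested genes (18.1%), where chance gives 10%. At an unadjusted p under 0.05 there were 902 higher and 497 lower genes, an excess of higher genes that depended on scaling: 765 and 633 with quantile normalization, 734 and 683 with median-ratio scaling, 735 and 646 with the abundant genes left out, 688 and 446 with equal totals, and 663 and 701 with upper-quartile scaling. The count rested on single libraries: without control replicate 1 it was 2, without control replicate 2 it was 30, without atorvastatin replicate 1 it was 13 and without atorvastatin replicate 3 it was 17, and without atorvastatin replicate 2 the calls were 9 higher and 52 lower. With no filter on low values 2 genes passed. Of the named called genes, 26 of 27 could be fitted with a library left out, and the call was lost by 24 without control replicate 1, 13 without control replicate 2, 7 without control replicate 3, and 17, 6 and 16 without atorvastatin replicates 1, 2 and 3. Of the genes whose fits with a library left out are not given below, Igtp, Ifi44 and Rgcc lost the call in 5 of 6, Gbp3, Gbp6 and Slfn2 in 4, Resp18, Stmn1, Tcf19 and Zbp1 in 3, Ccdc71, H2-Q5, Psmb8 and Rcbtb1 in 1 (without control replicate 1), Zbtb4 in 2 of 3 and Slfn5 in 1 of 3. With the 20 most abundant and the mitochondrially encoded genes left out before scaling, 15 genes were higher and 39 lower.

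The largest called decrease was in Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634, plus strand). It fell from 6.88 ± 1.33 FPKM in control to 0.918 ± 0.398 with atorvastatin (n = 3 each), a log2 fold change of -2.04 ± 0.17 (limma adjusted p = 0.0168). Without control replicate 1 the adjusted p of Iigp1 was 0.0533, in a range of 0.00652 to 0.136 over its alternatives. Igtp, of the same GTPase family, had a log2 fold change of -1.01 (limma adjusted p = 0.029). Igtp overlaps the annotated span of Irgm2, another member called lower, so their reads cannot be told apart with certainty. The Schlafen genes Slfn2 and Slfn5 fell with log2 fold changes of -1.55 and -1.18, and Trim30a, an interferon-inducible ubiquitin ligase gene, with -1.02 (limma adjusted p = 0.0477). Trim30a lay at the threshold and passed in 6 of 20 alternatives (0.00663 to 0.261), and among the fits with a library left out only without atorvastatin replicate 2. Ccdc71 fell from 5.27 ± 0.22 to 1.73 ± 0.42 FPKM, and Rcbtb1 from 8.19 ± 0.28 to 4.47 ± 0.09 FPKM.

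The list of interferon-stimulated genes passed camera's test downward. All 30 tested members of the list of 31 had negative fold changes, with a median log2 fold change of -0.81 (camera adjusted p = 9.97e-39). The adjusted p was 0.274 with an estimated correlation and 0.0454 with fry. Of these, 8 passed the test over all genes and 28 when adjusted over the list alone. The group difference of the list mean was -0.865 (95% interval -1.34 to -0.391), -0.885 (-1.87 to 0.102) with the T and NK cell score in the model and -1.27 (-2.35 to -0.192) with the level of mitochondrial ribosomal RNA. Ifit2, which binds RNA and restricts viral translation, fell from 5.50 ± 0.80 to 1.59 ± 0.55 FPKM (log2 fold change -1.34 ± 0.16, limma adjusted p = 0.029). The adjusted p of Ifit2 ran from 0.0139 to 0.195 over its alternatives and was under 0.05 with atorvastatin replicate 2 left out, but not with any other library left out. Ifi44 fell from 5.47 ± 0.51 to 1.45 ± 0.66 FPKM, and the guanylate-binding protein gene Gbp3 from 4.98 ± 0.76 to 1.66 ± 0.50 FPKM. Zbp1, a sensor of Z-form nucleic acid, fell from 8.91 ± 0.85 to 4.63 ± 0.41 FPKM, and Gbp6 from 2.47 ± 0.38 to 0.972 ± 0.142 FPKM. The Gbp, Slfn and Ifit genes lie in families of similar sequence, so the value of a single member is uncertain. Markers of T and NK cells, B and plasma cells and mast cells moved in the same direction, and their values are given below.

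The MHC class II list also passed downward. H2-Ab1, the beta chain of the class II molecule I-A (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419, plus strand), fell from 8.97 ± 1.23 to 3.17 ± 0.56 FPKM, a log2 fold change of -1.26 ± 0.12 (limma adjusted p = 0.0184). Its adjusted p was 0.073 without control replicate 1 and 0.0524 without atorvastatin replicate 1, in a range of 0.00652 to 0.136. The 6 tested members of the MHC class II list of 10 all had negative fold changes, with a median of -1.15 (camera adjusted p = 2.53e-11). The adjusted p was 0.274 with an estimated correlation and 0.0454 with fry. H2-Ab1 alone passed over all genes, and all 6 passed when adjusted over the list alone. The group difference of the list mean was -1.06 (95% interval -1.59 to -0.54), -0.686 (-1.31 to -0.0653) with the T and NK cell score in the model and -0.342 (-0.574 to -0.11) with the level of mitochondrial ribosomal RNA, both given below. Among those that did not pass over all genes, Cd74, the invariant chain, had 32.5 and 10.1 FPKM in control and atorvastatin, H2-Aa had 6.94 and 2.24 FPKM and H2-DMb1 had 3.85 and 1.76 FPKM. In the class I pathway, the immunoproteasome subunit gene Psmb8 fell from 9.94 ± 0.30 to 5.62 ± 0.51 FPKM (log2 fold change -0.73 ± 0.07, limma adjusted p = 0.0184), and H2-Q5 from 4.34 ± 0.18 to 2.11 ± 0.21 FPKM. H2-Q5 belongs to a cluster of near-identical genes and its own level is uncertain.

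Most leukocyte markers were low in these epithelial isolates. Exceptions included Ly6g, at 26.4 and 19.5 FPKM in control and atorvastatin, and Cd14, at 14.2 and 14.9 FPKM. The T and NK cell, B and plasma cell and mast cell lists passed camera's test downward, with no member past the test over all genes. The 9 tested T and NK cell genes, of 18 on the list, all had negative fold changes, with a median of -0.44 (camera adjusted p = 4.38e-08, and adjusted p = 0.364 with an estimated correlation). The call was lost with a filter of 5 FPKM, which tests fewer genes, at a median of -0.70 (camera adjusted p = 0.147). When adjusted over the list alone 3 members passed. Gzmb, a granule protease of cytotoxic lymphocytes, had 6.33 and 3.10 FPKM in control and atorvastatin, Lck had 2.37 and 1.69 FPKM, Nkg7 had 2.25 and 1.23 FPKM and Klrd1 had 1.85 and 1.07 FPKM. In the B and plasma cell list (2 tested of 15, camera adjusted p = 0.000726, and adjusted p = 0.314 with an estimated correlation), Igkc had 5.75 and 1.71 FPKM and Igha had 2.03 and 0.562 FPKM. This call was lost without control replicate 2 (camera adjusted p = 0.0897) and with no filter (median -0.006, camera adjusted p = 0.0984). In the mast cell list (3 tested of 11, camera adjusted p = 0.00383, and adjusted p = 0.364 with an estimated correlation), the mucosal mast cell proteases Mcpt1 and Mcpt2 had log2 fold changes of -1.92 and -1.58, while Kit stayed near 0. This call, at a median of -1.58, was lost without control replicate 1 (median -0.91, camera adjusted p = 0.0593), without control replicate 2 (-0.82, 0.147) and with a filter of 5 FPKM (-0.003, 0.939). Both members of the B cell list and 2 of the mast cell list passed when adjusted over the list alone. Ptprc, which encodes the pan-leukocyte protein CD45, was at 1.81, 1.98 and 1.15 FPKM in control and 0.688, 0.824 and 1.17 FPKM with atorvastatin (limma adjusted p = 0.275). The macrophage and dendritic cell list did not pass (3 tested, camera adjusted p = 0.207), and at a pseudocount of 0.1 its 7 genes with a mean of at least 0.3 FPKM had a median of -0.699, with 5 of 7 lower. The mitochondrial ribosomal RNAs, named after their values were seen and whose level varies with library preparation, were also lower in each atorvastatin library, at 2156, 2631 and 1828 FPKM in control and 1195, 1160 and 1526 FPKM with atorvastatin for mt-Rnr1, and at 2054, 2536 and 2078 against 1562, 1294 and 1722 FPKM for mt-Rnr2 (limma adjusted p = 0.115 and 0.153).

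**Figure D1:**
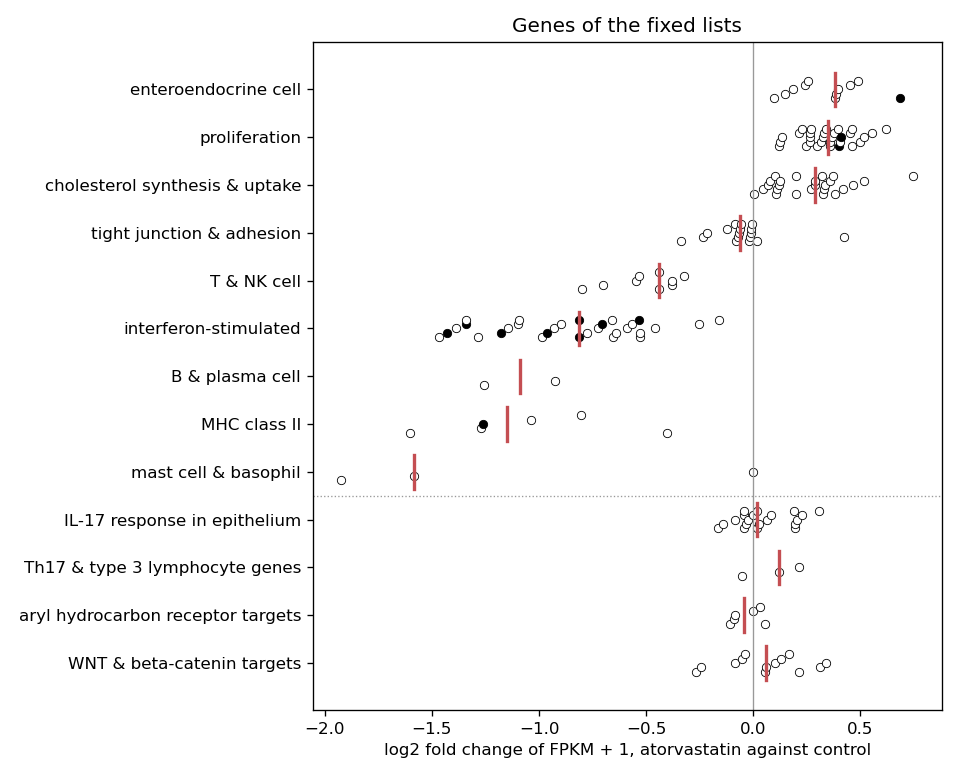
Log2 fold change of FPKM + 1 (atorvastatin against control, horizontal axis) for each tested gene of the 9 lists that passed camera (above the dotted line) and 4 lists on interleukin 17, the aryl hydrocarbon receptor and WNT (below it). Filled circles are genes past the test over all genes and red bars are list medians. The interferon-stimulated list has a median of -0.81 with all 30 genes below 0, and the proliferation list one of 0.35 with all 30 genes above 0.

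Among the genes that rose, Cyp2c55, a cytochrome P450 expressed in the colon (ENSMUSG00000025002, chromosome 19, 39007019 to 39042693, plus strand), was the most abundant. It rose from 217 ± 30.5 to 525 ± 81 FPKM, a 2.42-fold increase of the means (log2 fold change 1.27 ± 0.14, limma adjusted p = 0.0237). Its call was lost without control replicate 1 (limma adjusted p = 0.113), without atorvastatin replicate 2 (0.0542) and without atorvastatin replicate 3 (0.067), with a range of 0.017 to 0.161 over its alternatives. It was the single called member of the xenobiotic and PXR target list, whose camera test did not pass (16 tested, median 0.08, adjusted p = 0.129) but did without control replicate 2 (camera adjusted p = 0.00847), without atorvastatin replicate 1 (0.000838) and with no filter (0.0272). Rap1gap2, an activating protein for the GTPase Rap1 (ENSMUSG00000038807, chromosome 11, 74383356 to 74610915, minus strand), rose from 6.33 ± 0.23 to 16.05 ± 0.73 FPKM (log2 fold change 1.22 ± 0.06, limma adjusted p = 0.000835). Grhl2, an epithelial transcription factor gene (ENSMUSG00000022286, chromosome 15, 37233036 to 37363569, plus strand), rose from 6.24 ± 0.22 to 12.9 ± 0.3 FPKM (log2 fold change 0.94 ± 0.05, limma adjusted p = 0.00146). Without control replicate 1, 2 genes passed, Rap1gap2 and Grhl2. Zbtb4 rose from 0.515 ± 0.090 to 1.76 ± 0.25 FPKM, and Usp43, a deubiquitinase gene, from 7.22 ± 0.83 to 11.5 ± 0.1 FPKM. Usp43 lost its call without any of control replicates 1, 2 and 3 (limma adjusted p = 0.0504, 0.0895 and 0.0523) and atorvastatin replicates 1, 2 and 3 (0.113, 0.067 and 0.131), with a range of 0.0255 to 0.195 over its alternatives.

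The proliferation list passed camera's test upward, with 2 members called. All 30 members had positive fold changes, with a median of 0.35 (camera adjusted p = 5.35e-15, adjusted p = 0.364 with an estimated correlation, and 0.113 with fry). When adjusted over the list alone 13 members passed. The group difference of the list mean was 0.346 (95% interval 0.00659 to 0.686), 0.107 (-0.315 to 0.529) with the T and NK cell score in the model and 0.034 (-0.704 to 0.772) with the mitochondrial ribosomal RNA level. The replicative helicase genes Mcm5 and Mcm6 rose from 8.03 ± 0.32 to 10.998 ± 0.318 FPKM and from 11.1 ± 0.7 to 15.01 ± 0.24 FPKM (limma adjusted p = 0.0314 and 0.0477). Mcm6 lay at the threshold and passed in 3 of 20 alternatives (limma adjusted p 0.0367 to 0.231). Mcm5 passed in 12 of 20 (0.0273 to 0.195), and among the fits with a library left out only without control replicate 3. Mki67, which encodes the proliferation marker Ki-67, had 28.0 ± 4.9 and 38.9 ± 5.3 FPKM (limma adjusted p = 0.256). Rrm2 and Tk1, enzymes of nucleotide supply, had log2 fold changes of 0.62 and 0.55 and did not pass over all genes. Outside the list, Stmn1, which encodes the microtubule-destabilizing protein stathmin, rose from 19.9 ± 0.7 to 30.3 ± 2.0 FPKM, Tcf19 from 3.07 ± 0.25 to 5.56 ± 0.45 FPKM and Rgcc from 1.89 ± 0.18 to 3.21 ± 0.03 FPKM.

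The cholesterol synthesis list passed camera's test upward, with no member called singly. All 25 targets of the sterol-responsive factor SREBP2 had positive fold changes (24 of 25 under quantile, median-ratio and upper-quartile scaling), with a median of 0.29 (camera adjusted p = 8.93e-11, adjusted p = 0.314 with an estimated correlation, and 0.0662 with fry). None passed over all genes in limma's test, and 12 passed when adjusted over the list alone. The group difference of the list mean was 0.263 (95% interval 0.106 to 0.421), 0.157 (-0.0516 to 0.365) with the T and NK cell score in the model and 0.158 (-0.24 to 0.556) with the mitochondrial ribosomal RNA level. The isoprenoid enzyme genes Fdps and Idi1 had log2 fold changes of 0.47 ± 0.07 and 0.32 ± 0.06, and the sterol demethylase gene Cyp51 0.29 ± 0.05. Sqle had 22.6 ± 1.9 and 29.2 ± 1.4 FPKM, and Hmgcs1 102 ± 2.2 and 129 ± 16.5 FPKM (limma adjusted p = 0.112 and 0.205). Insig1, at 59.9 ± 1.5 and 69.3 ± 10.5 FPKM, did not pass either.

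The list of enteroendocrine genes, which mark the hormone-producing cells of the epithelium, passed camera's test upward. All 11 tested members of the list of 17 had positive fold changes, with a median of 0.38 (camera adjusted p = 9.83e-07). The adjusted p was 0.169 with an estimated correlation and 0.0116 with fry. The group difference of the list mean was 0.339 (95% interval 0.251 to 0.427), 0.276 (0.168 to 0.384) with the T and NK cell score in the model and 0.238 (0.092 to 0.384) with the mitochondrial ribosomal RNA level. Gcg, which encodes proglucagon, the precursor of GLP-1 in the colon, passed over all genes and rose from 15.996 ± 0.629 to 26.5 ± 3.4 FPKM (log2 fold change 0.69 ± 0.09, limma adjusted p = 0.0401). It lost its call without any of control replicates 1, 2 and 3 (limma adjusted p = 0.167, 0.0984 and 0.0728) and without atorvastatin replicates 1 and 2 (0.113 and 0.0955), with a range of 0.0178 to 0.231 over its alternatives. When adjusted over the list alone 6 members passed, among them Pyy, at 8.58 ± 0.96 and 12.5 ± 1.2 FPKM, Chga, at 13.1 ± 1.2 and 18.4 ± 2.0 FPKM, and Chgb, at 44.9 ± 3.3 and 58.9 ± 6.5 FPKM. Resp18, a secretory granule protein gene of neuroendocrine cells, rose from 1.11 ± 0.15 to 2.51 ± 0.19 FPKM.

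The tight junction and adhesion list passed downward by a small amount, with a median of -0.06 over 17 tested genes, 15 of them negative and 16 under median-ratio and upper-quartile scaling (camera adjusted p = 0.0174, and adjusted p = 0.451 with an estimated correlation). The call was lost without control replicate 2 (camera adjusted p = 0.109) and without atorvastatin replicate 3 (0.0946). No member passed over all genes in limma's test, and 1 passed when adjusted over the list alone, Cldn8, against the direction of the list at 41.1 ± 4.2 and 55.5 ± 5.1 FPKM. Marveld3, Cldn23 and Marveld2 had log2 fold changes of -0.21, -0.23 and -0.34.

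**Figure D2:**
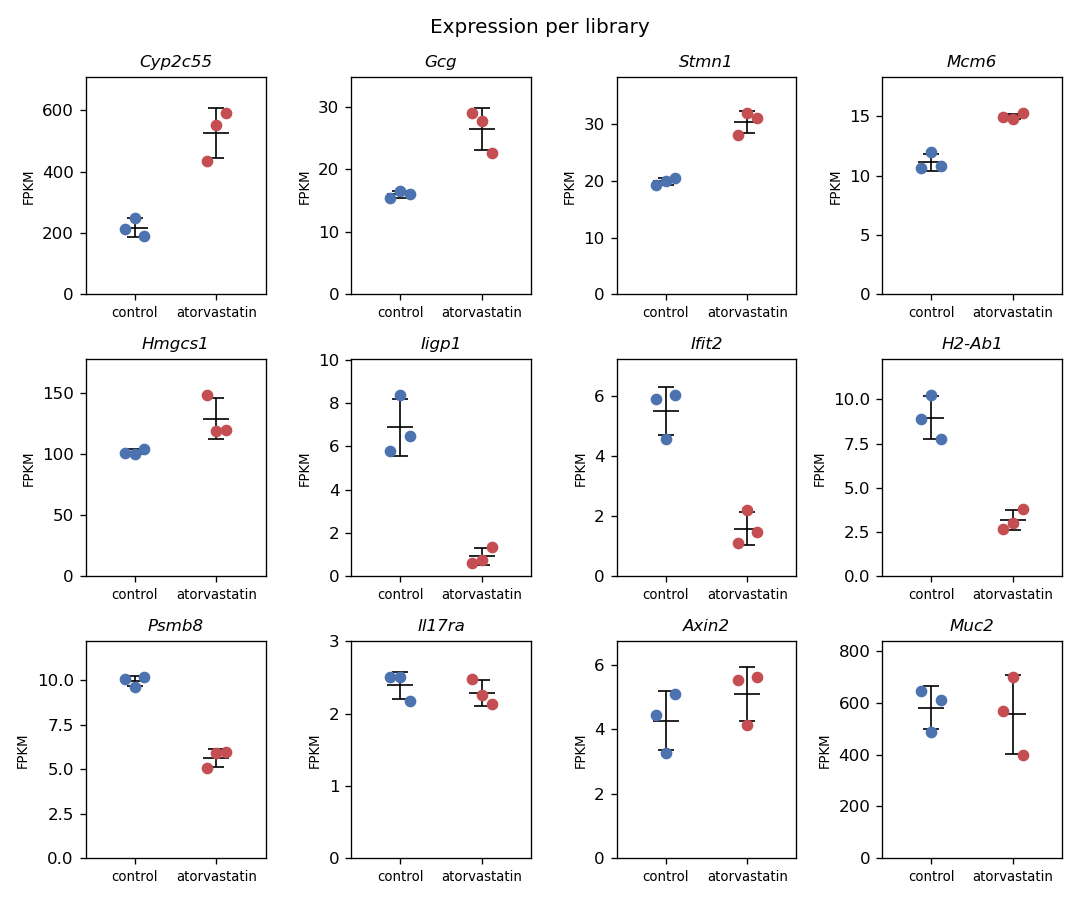
FPKM of 12 genes in each library (points), with the mean and SD of 3 libraries (bars), for control and atorvastatin, on linear axes from 0. Cyp2c55, Gcg, Stmn1 and Mcm6 lie higher with atorvastatin and Iigp1, Ifit2, H2-Ab1 and Psmb8 lower, without overlap. Hmgcs1 lies higher without passing the test, and Il17ra, Axin2 and Muc2 overlap.

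Genes of the interleukin 17 and tryptophan pathways, on which the series focuses, did not pass as lists. The epithelial interleukin 17 response list had a median of 0.02 over 20 tested genes (camera adjusted p = 0.587), with no member past the threshold over all genes or when adjusted over the list alone. Il17ra, a receptor subunit for interleukin 17, had 2.39 ± 0.18 and 2.29 ± 0.18 FPKM. Il17a was listed at 0.0932, 0.0234 and 0.0204 FPKM in control and at 0, 0.023 and 0.0923 FPKM with atorvastatin, below the level tested. The list of type 3 lymphocyte genes had a median of 0.12 over 3 tested members (camera adjusted p = 0.805), and passed in the other direction with no filter (median -0.033, camera adjusted p = 0.00208) and with a filter of 0.1 FPKM (-0.14, 0.0205). Aryl hydrocarbon receptor targets, which respond to indole ligands, had a median of -0.04 over 6 tested genes (camera adjusted p = 0.304), and Cyp1a1 was listed at 0 in 5 libraries and at 0.0194 FPKM in atorvastatin replicate 3. The tryptophan metabolism list had a median of -0.01 and a mean of 0.03 over 8 tested genes, and its camera test pointed up (adjusted p = 0.982).

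WNT and beta-catenin targets, which are activated when Apc is lost, had a median of 0.06 over 13 tested genes (camera adjusted p = 0.571), with no call over all genes. Lgr5, a crypt stem cell marker, was at 0.675 ± 0.042 and 1.08 ± 0.07 FPKM (log2 fold change 0.31 ± 0.07, limma adjusted p = 0.142) and was the 1 member past the threshold when adjusted over the list alone. Smoc2, also a crypt stem cell marker, had 0.34 ± 0.09 (limma adjusted p = 0.207). Axin2 was at 4.28 ± 0.92 and 5.09 ± 0.84 FPKM (limma adjusted p = 0.666). Apc itself was listed at 10.6, 4.95 and 10.1 FPKM in control and at 5.24, 5.65 and 5.41 FPKM with atorvastatin (limma adjusted p = 0.492). With control replicate 2 left out, Apc passed (limma adjusted p = 0.0199). The epithelial marker Epcam had 555 ± 18 and 510 ± 28.5 FPKM and the goblet cell mucin gene Muc2 581 ± 83.1 and 555 ± 151 FPKM, neither past the threshold (limma adjusted p = 0.505 and 0.911).

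**Figure D3:**
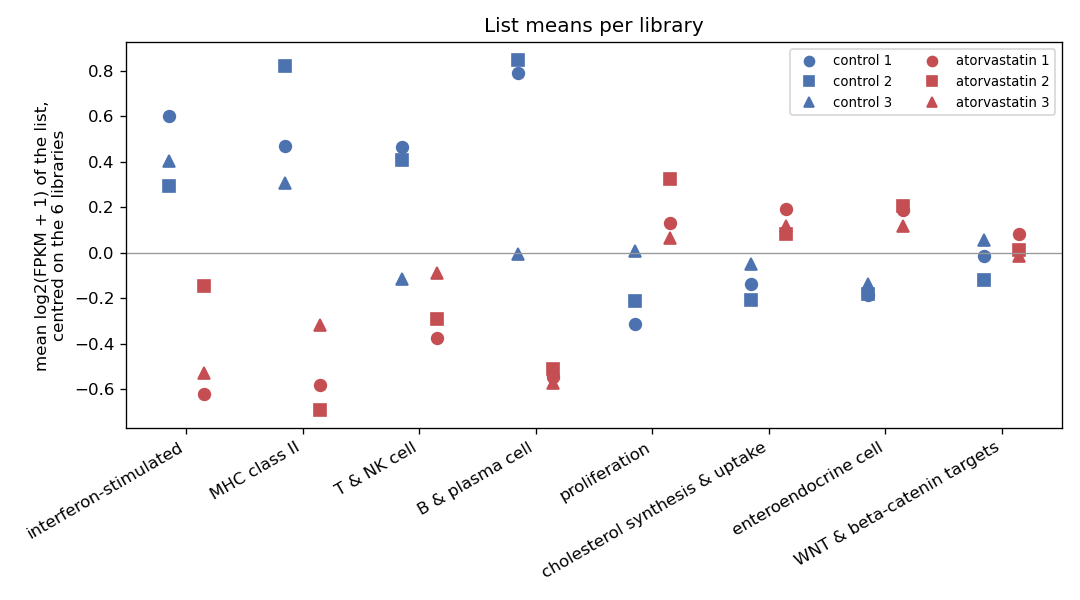
Mean log2(FPKM + 1) of 8 gene lists in each library, centred on the 6 libraries (vertical axis), with control in blue and atorvastatin in red and a symbol per replicate number. The groups do not overlap in the interferon-stimulated, MHC class II, B and plasma cell, proliferation, cholesterol and enteroendocrine lists. In the T and NK cell list control replicate 3 (-0.12) lies among the atorvastatin libraries, and the groups also overlap in the WNT list.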

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

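The filter at 5 FPKM, the fit without the robust option, equal totals and the fit without 2-level genes were chosen after seeing the data. The 47 calls (18 higher, 29 lower) became 2 (2 higher, 0 lower) with no filter, where limma gave 951 lower genes at an unadjusted p under 0.05. There were 142 (77 higher, 65 lower) at an adjusted p under 0.10, and 12 (2 higher, 10 lower) with an absolute log2 fold change of at least 1. Leaving out each library in turn gave 2 to 67 changed, 2 to 25 higher and 0 to 52 lower genes. The 0 came without control replicate 1, with 367 lower genes at an unadjusted p under 0.05 in limma, and these fits had fewer libraries. The 5 FPKM filter left 19 lower genes of 6697 tested, and without 2-level genes 10 were higher. Same-numbered libraries did not deviate together (correlations of their deviations from the group means of -0.139, -0.106 and 0.0136), so the numbers were not taken as pairs, and with a replicate block limma called 1 gene, 1 higher and 0 lower (402 lower at an unadjusted p under 0.05). No library correlated best with its own number. Of the 9 lists, 0 passed camera with an estimated correlation (4 at an unadjusted p under 0.05) and 3 passed fry. The gap on the first component was 27% over the 500 most variable genes. The type 3 lymphocyte list passed downward with no filter (median -0.033, camera adjusted p = 0.00208) and at 0.1 FPKM in 3 libraries (median -0.14, camera adjusted p = 0.0205). Of the lists that did not pass, fatty acid oxidation passed in 9 of 21 settings, fatty acid synthesis in 4, xenobiotic targets in 3, KLF2 and RHOB, colonocyte and macrophage lists in 2 each. More leukocyte genes enter the fits with a lower filter; the cause was not tested. The other settings of filter, pseudocount, scaling, weights and robust option kept 32 to 46 of the 47 calls, and no named called gene changed direction. The median log2 fold change of all genes stayed between -0.00365 and 0.0184 under the scalings, quantile normalization included. Count models, count-based normalizations and weights and a CPM filter, listed in advance, were not run because the values are FPKM. The unknown depth leaves the error of genes near 1 FPKM to the 3 libraries alone. For the moved counts, the cause was not tested beyond the fewer libraries or genes each setting leaves.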

Other observations

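The tests of scaling, of library preparation, of crypt-base cells, of leukocytes as a source of the proliferation change, and of B cells and macrophages for class II were chosen after the results they bear on were seen. Some goblet cell and antimicrobial genes varied widely between libraries, and neither list passed with all libraries. Ang4, an antimicrobial ribonuclease gene, had 37.1 ± 41.5 and 112 ± 55.3 FPKM in control and atorvastatin, and Retnlb, a goblet cell peptide gene, 24.8 ± 9.5 and 72.7 ± 38.2 FPKM (limma adjusted p = 0.379 and 0.302). The goblet cell list had a median of 0.10 and a mean of 0.28 (17 tested, camera adjusted p = 0.153, and 0.0146 without atorvastatin replicate 3). Its mean per library, centred on the 6 libraries, was -0.20, -0.03 and -0.19 in control and 0.12, 0.17 and 0.13 with atorvastatin, without overlap. The antimicrobial list had a median of 0.04 and a mean of 0.34 (11 tested, camera adjusted p = 0.996). Colonocyte genes had a median of -0.03 (21 tested, camera adjusted p = 0.0776, 0.00797 without control replicate 3 and 0.0203 without atorvastatin replicate 2), with Lypd8 at 4831 ± 580 and 3716 ± 474 FPKM. The abundant class I light chain gene B2m, named after its values were seen, fell from 405 ± 43.2 to 260.5 ± 11.7 FPKM (limma adjusted p = 0.0428).

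Lists of fatty acid synthesis and LXR targets (median 0.13, camera adjusted p = 0.0763), fatty acid oxidation (-0.04, 0.0503) and KLF2 and RHOB statin response genes (-0.09, 0.3) did not pass. The fatty acid oxidation list lay at the threshold and passed downward in 9 of 21 alternatives, among them median-ratio scaling (camera adjusted p = 0.0414), upper-quartile scaling (0.0346), the fit with the abundant genes left out (0.0313), and the fits without control replicates 1 and 3 (0.00883 and 0.00797) and atorvastatin replicate 3 (0.0211). The fatty acid synthesis list passed upward in 4, with the replicate block (0.0425), without control replicates 1 and 3 (0.0282 and 0.017) and without atorvastatin replicate 1 (0.0167). The KLF2 and RHOB list passed downward in 2, without control replicate 1 (0.0453) and without atorvastatin replicate 1 (0.0258). Apoptosis and p53 targets (-0.02, 0.3), small intestinal and Paneth cell genes (0.12, 0.775), immediate early and heat shock genes (-0.03, 0.151, and 0.0106 without control replicate 1) and mitochondrially encoded protein genes (0.03, 0.481, and 0.0161 without atorvastatin replicate 2) did not pass with all libraries. The unfolded protein list had a median of -0.02, a mean of 0.02 and a camera test pointing down (adjusted p = 0.789). Macrophage (-0.04, 0.207), neutrophil (-0.36, 0.398), fibroblast (-0.10, 0.429), smooth muscle (0.02, 0.874) and adipocyte, erythroid and acinar (-0.09, 0.364, and 0.00355 without atorvastatin replicate 3) lists had 1 to 5 tested genes each and did not pass. The neutrophil value is that of Ly6g alone, the 1 tested gene of 13 on its list. With no filter the macrophage and neutrophil lists passed downward (camera adjusted p = 0.000844 and 0.00778), as did the macrophage list at 0.1 FPKM in 3 libraries (0.0257). Tuft cell, endothelial and enteric neuron lists had no gene past the filter.

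The lower interferon-stimulated and class II genes came with lower leukocyte markers. At a pseudocount of 0.1, the median log2 fold change was -1.03 for the 30 interferon-stimulated genes, -1.35 for 6 class II genes, -0.761 for 16 T and NK cell genes, -1.62 for 4 B and plasma cell genes, -0.699 for 7 macrophage and dendritic cell genes (5 of them lower) and -1.37 for 4 mast cell genes, with a mean of at least 0.3 FPKM. Scaling between libraries is argued against, since the interferon median nearest 0 over 4 scalings was -0.818. With the T and NK score in the model, the group difference was -0.885 for the interferon list (95% interval -1.87 to 0.102) and -0.686 for class II (-1.31 to -0.0653). The class II bound set in advance lay below 0 and was set aside after it was seen, because T and NK cells are a poor stand-in for class II-bearing B cells and macrophages, and with a score of their markers the difference was -0.701 (-1.72 to 0.314). Fewer leukocytes and lower epithelial expression therefore cannot be told apart with 3 libraries per group. With the mean of mt-Rnr1 and mt-Rnr2 in the model the interferon difference was -1.27 (-2.35 to -0.192), with a slope on the score of -0.62 (-2.08 to 0.844). Both RNAs were lower in each atorvastatin library than in any control library. The fit therefore cannot separate treatment from a difference in RNA or library preparation, and no conclusion is drawn from it for the interferon genes. For class II the group difference was -0.342 (-0.574 to -0.11), against -1.06 without the score. The slope on the score was 1.1 (0.786 to 1.42, a criterion added after the values were seen), so such a preparation difference cannot be told apart from treatment as a cause of part of the class II change. A drug effect on epithelial interferon signalling, with or without fewer interferon-producing lymphocytes, may underlie the change and was not tested.

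The higher proliferation genes may reflect more cycling epithelial cells. Dilution by fewer leukocytes would raise all epithelial genes alike, but the tight junction and adhesion list lay -0.41 from the proliferation list. The 95% bootstrap interval of this gap (-0.464 to -0.33) was drawn over genes and leaves out the spread between libraries. In these libraries the gap argues against dilution as the whole cause, without measuring how it would vary between libraries. Scaling is argued against too, since under 4 scalings the proliferation median nearest 0 was 0.324. The group difference fell from 0.346 to 0.107 (-0.315 to 0.529) with the T and NK score in the model. That interval includes 0.346, so the fit does not show whether the change moved with the leukocyte markers. A factor shared with them stays open. With the mitochondrial ribosomal RNAs in the model the difference was 0.034 (-0.704 to 0.772), and RNA or library preparation cannot be told apart from treatment with 3 libraries per group. Nor can a larger share of crypt-base cells. The WNT list median lay -0.289 from the proliferation median (-0.426 to -0.157), but its members went both ways (8 up, 5 down). The crypt-base markers Lgr5 and Smoc2, at 0.31 and 0.34, lay near the proliferation median of 0.35. Smoc2 had the largest value of the WNT list, which ran from -0.268 to 0.341. Lgr5, at 0.675 FPKM in control and 1.08 FPKM with atorvastatin, is understated on this scale. The nearness of these 2 markers to the proliferation median therefore carries little weight. A larger share of transit-amplifying cells was not tested.

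The calls with the smallest p in limma's test, Rap1gap2, Grhl2 and Rcbtb1, lay at 2 tight levels. A small spread within each group and a wide gap also give a small p, so this overlap is partly built in. On the treatment split, 7 tested genes had an SD of log2 FPKM of at most 0.1 within each group and a gap of at least 0.6, of which 5 were called: Rap1gap2, Grhl2, Rcbtb1, Stmn1 and Ube2e3 (the last named after its values were seen). The crypt-base marker Lgr5 was also among the 7 and was not called. The most frequent of the other 9 splits held 3, a ratio of 2.33. The ratio lies past the bound of 2 set in advance by less than the counting error of 7 genes, a criterion added after the count was seen, so discrete steps of quantification, such as a fragment set assigned to 1 transcript form or another, cannot be told apart from treatment. Apc also lay at 2 levels, which did not follow the treatment split: 4.95 FPKM in control replicate 2 and 5.24 to 5.65 FPKM with atorvastatin, against 10.6 and 10.1 FPKM in control replicates 1 and 3.

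The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The direction of the other splits is arbitrary, so the larger of both directions was taken as higher and as lower for each. The real split gave 47 genes and the highest other 5 (1 split with as many), 18 higher against 4 (1 split) and 29 lower against 4 (1 split). For gene lists the real split gave 9 and the highest other 15, and 3 of the 10 splits gave as many.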
